A study of Rattus norvegicus with 10 samples.

How the data were processed

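Gene expression was measured with the Affymetrix Rat Genome 230 2.0 array in the hearts of male Fischer-344 rats of 2 ages, 6 months (adult, 5 arrays) and 24 months (aged, 5 arrays). Per the labels' protocols, total RNA was extracted with TRIzol, purified on an affinity column, amplified over 2 rounds of cDNA synthesis and labelled with biotin. The sample protocols name the whole heart as the source, whereas the series text names the ventricles, so whether atria were included is not settled by the labels. The labels state neither batch, scan date nor time of day. They also do not say outright that each array holds RNA of a separate rat, so p-values measure the spread between these samples.

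The authors' deposited table holds 1 signed log value for each of 31042 probe sets on each of the 10 arrays, and these values were used as log2 values. The log base is not stated in the labels. It was inferred from the numerical step of the values, which has the size that single-precision log2 array intensities would have. The software, background correction and normalization behind the table are not given in the sources used here. Every probe set had a median of 0 over the 10 arrays, within a tolerance of 1e-06, so the table keeps differences between arrays but no absolute level. The numerical step was taken as a trace of it, from which 3 approximate classes were inferred. By the lowest value of each probe set, 4925 probe sets (15.87%) were placed in a class that would hold values between 2 and 4 before centring, 22574 (72.72%) between 4 and 8, and 3543 (11.41%) at 8 or more. As a check of direction, 315 probe sets with a range above 1 changed class on up to 3 arrays. The arrays in the lower class had the lower ranks in 230 of them (73.02%) and the higher ranks in 81, which exact classes would not give, so classes of single values are uncertain. Of the 77 nuclear-encoded subunits of oxidative phosphorylation, which are abundant in heart, 75 had a probe set in the brightest class, against 19.4% of all genes. All settings that use the classes carry this uncertainty. The table used held 0 Affymetrix control probe sets, so the planned 3' to 5' ratios of RNA integrity were not analysed here. The array medians were the only measure of array quality. Signal over background was not analysed here, and for arrays their number limits the precision. The highest correlation between any 2 arrays was 0.570, and each array was counted as 1 sample.

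Probe sets were named through the platform annotation table, with symbols updated by gene identifier through a RefSeq gene table of assembly GRCr8, used for names alone. In it, 20826 probe sets had 1 gene symbol, 436 had several and 9780 had none listed, and 20758 of the single-gene probe sets matched the reference by identifier. Probe sets with several genes were named for none. The 14217 genes so named were each given the mean of their probe sets. For 3 genes, Pnn, Smarcc2 and Vps41, chosen after their values were seen, probe sets passed the test in opposite directions.

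Aged and adult arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 10 arrays, no covariate and Benjamini-Hochberg adjustment, over probe sets and again over genes. The prior degrees of freedom were 5.09. A gene is described as risen or fallen where its adjusted p over all 14217 genes was under 0.05. Gene values are given as the log2 difference, aged minus adult, with its standard error (SE). Gene lists for metabolic pathways, tissue processes and cell types, 43 in number, were fixed together with the test, the rule for named genes and a set of other settings before the data were examined. The list of mitochondrially encoded subunits had 2 measured members and was not tested. A union, fixed with them, of all nuclear-encoded subunits of complexes I to IV and ATP synthase was added, which left 43 lists tested. Lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 43 lists. In other groupings of the arrays a median of 13 lists passed this test. Beside it stand camera with the correlation estimated from the data and an exact two-sided permutation test of the list score per array. The list score is the mean over members of each log2 value minus that gene's mean over the 10 arrays. The arrangements of 5 arrays against 5 allow no p below 0.00794, and the permutation p of each list was adjusted over the 43 lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to prepare the tables and to draw the plots.

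The genes named were the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose aged and adult values did not overlap and whose probe sets were not all in the dimmest class. Of each list, up to 4 members with the smallest p were named, and up to 6 for the complexes, the TCA cycle, pyruvate oxidation and the fatty acid list, as were all members of a list with fewer than 5 measured genes. Unnamed loci were counted but not named, and any other gene named is said to have been chosen after its values were seen. Centring forced several departures from the plan. The plan represented a gene by its brightest probe set on average, and the mean of all its probe sets, a setting also fixed beforehand, was used in its place. A planned condition on brightness of named genes was replaced by the one on the dimmest class, and the planned mean-level filter and variance trend could not be applied.

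The comparison was tested on simulated data, with noise drawn independently for each probe set at its real residual SD. With 100 of 31042 probe sets shifted by 0.4 on the log2 scale, 72% were recovered. With another 100 shifted by 0.8, 97% were recovered, and 14 unchanged probe sets were called. In the simulated lists, all nuclear-encoded subunits were shifted by -0.15, and their list was recovered. Leaving aside the lists of the single complexes and ATP synthase, which were shifted with it, 0 of the other lists passed camera. The simulated genes were uncorrelated, whereas the correlation estimated from the data was 0.607 for complex I. The simulation therefore cannot show how often correlated lists pass camera without a real shift. The other settings fixed beforehand were quantile normalization, centring of each array on its median, array weights, other thresholds, each array left out in turn, the replicate number as a block, other set tests, and the median over members as the list score. Settings added after the data were seen were leaving out 3598 probe sets in the dimmest class on at least 3 arrays, taking the probe sets of the brightest class of each gene, and a robust eBayes fit. Also added were leaving out the 2 aged arrays with the highest lymphocyte marker score and leaving out arrays for the list scores and array medians.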

Results

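Expression of 14217 named genes was measured in hearts of male Fischer-344 rats, an inbred laboratory strain widely used in research on aging. There were 5 adult samples at 6 months and 5 aged samples at 24 months. The series was designed to profile genes of substrate metabolism and oxidative phosphorylation in the mitochondria at both ages. All values are log2 differences from the median of the 10 arrays, with the log base inferred from the values, so they show differences between arrays and no absolute level. The median value of an array lay between -0.0061 and 0.0093 in the adult group and between -0.0097 and 0.0038 in the aged group. The difference of -0.00623 between the group means was within what regrouping the arrays gives (two-sided exact permutation p = 0.111). Without adult replicate 4 the exact permutation p was 0.0397.

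Among genes whose aged and adult values did not overlap, those that differed most between the ages included genes of a natriuretic peptide, matrix proteins, immune proteins and myosins. Bex1, which encodes a small adaptor protein, was 7.58-fold higher in aged hearts (log2 2.92 ± 0.20 SE, adjusted p = 4.07e-05, n = 5 per age). Nppa, which encodes atrial natriuretic peptide, was 6.45-fold higher (2.69 ± 0.38 SE, adjusted p = 0.00179). Postn and Ccn2, which encode the matricellular proteins periostin and connective tissue growth factor, rose by 2.26 and 2.09. Among the other large rises were the serine protease gene Gzma of cytotoxic lymphocytes (1.98, with a value of 3.38 in aged replicate 3), Chi3l1 (1.88), the amine oxidase gene Maoa (1.54) and the B-cell chemokine gene Cxcl13 (1.38). Rises of similar size were seen in Ecrg4 (1.36), the leukocyte adhesion gene Vcam1 (1.36), the myosin light chain gene Myl1 (1.35) and the glutathione transferase gene Gsta1 (1.34). The deepest falls among such genes were in Fxyd3 (-1.33), a regulator of the sodium pump, and in Myh6 (-1.24), the fast alpha myosin heavy chain of the heart, whose 2 probe sets gave -2.02 and -0.46. Dhrs7c (-1.10), Wfdc1 (-1.09), the pyruvate dehydrogenase phosphatase gene Pdp2 (-1.05), Dcxr (-1.04) and Ddit4l (-1.01) also fell. So did the vessel growth factor gene Angpt1 (-0.94), Mlf1 (-0.89), the heme synthesis gene Alas1 (-0.86), the branched-chain aminotransferase gene Bcat2 (-0.85) and Klhl33 (-0.84). For each of these 24 genes every aged array lay on 1 side of every adult array. Most changes were smaller than these. By limma, 1686 genes (11.9%) changed, 962 upward and 724 downward, with a median size of 0.34 (1.27-fold). Of these, 248 changed by at least 1.5-fold, 192 upward and 56 downward. The ages did not overlap in 1409 genes (9.91%, against 0.794% by chance). Per probe set, 2492 of 31042 changed, 1373 upward and 1119 downward. Single arrays moved these counts. Without adult replicate 2, 1047 genes and 1553 probe sets were called, and without adult replicate 3, 988 and 1492. The counts were 1003 and 1481 without aged replicate 5 and 1089 and 1618 without aged replicate 6. The call of Gzma was lost without adult replicate 2 (adjusted p = 0.0545) or 3 (0.0523). That of Bcat2 was lost without adult replicate 1 (0.0520), 2 (0.0747) or 3 (0.0568) or aged replicate 5 (0.0509).

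Genes for the nuclear-encoded subunits of the respiratory chain and ATP synthase, the machinery that the series set out to profile, were mostly lower in aged hearts, by small amounts. Of 77 subunits, 62 had a lower mean in aged hearts, 16 fell (18 when adjusted over the list alone) and 61 did not pass the test. Their mean change was -0.10, or -6.95% (camera adjusted p = 1.11e-06). It gave adjusted p = 0.499 with an estimated correlation and 0.0853 by the exact permutation test of the score. In complex I, the NADH dehydrogenase, 6 of 34 subunits fell and 7 did when adjusted over the list alone. The smallest p were those of Ndufs1 (-0.38 ± 0.07 SE, adjusted p = 0.00621) and Ndufv1 (-0.35 ± 0.06 SE, adjusted p = 0.00524), which encode subunits of its NADH-oxidizing arm. The list gave a camera adjusted p of 7.86e-05, with adjusted p = 0.530 with an estimated correlation and 0.118 by permutation. Of the 4 complex II subunits, the succinate dehydrogenase flavoprotein gene Sdha fell (-0.28, adjusted p = 0.0306). When adjusted over the list alone 2 fell, and all 4 had lower means (camera adjusted p = 0.0168, adjusted p = 0.446 with an estimated correlation, 0.0244 by permutation). In complex III, 3 of 8 subunits fell by either adjustment over all genes or adjusted over the list alone. They were Cyc1 (-0.42), which encodes cytochrome c1, and the core subunit genes Uqcrc1 (-0.26) and Uqcrc2 (-0.20). As a list, complex III did not pass camera (mean -0.13, adjusted p = 0.0601). Complex IV, the cytochrome oxidase, had 1 of 15 subunits that fell, Cox5a (-0.26), also when adjusted over the list alone. That list did not pass either (mean -0.04, camera adjusted p = 0.223), and its mean was -0.02 without adult replicate 1 (0.413) and -0.06 without aged replicate 2 (0.0801). In ATP synthase, 5 of 16 subunits fell and 6 did when adjusted over the list alone, among them Atp5f1d (-0.27) and Atp5f1b (-0.19) of its catalytic part. The list passed camera (mean -0.10, camera adjusted p = 0.00176, adjusted p = 0.446 with an estimated correlation, 0.0742 by permutation). The mitochondrially encoded COX1 and COX2 gave 0.00 ± 0.04 SE (adjusted p = 0.968) and 0.03 ± 0.04 SE (adjusted p = 0.696). Aged replicate 2 scored 0.13 for complex I, above the highest adult array at 0.10, and aged replicate 3 scored -0.18, the lowest of the 10 arrays. The complex II list did not pass without aged replicate 3 (adjusted p = 0.0501), and complex III passed without adult replicate 2 (0.0389) or aged replicate 2 (0.0145). The call of Sdha was lost without adult replicate 2, 3 or 4 or aged replicate 3, 5 or 6 (0.0543 to 0.0817), as was that of Uqcrc2 without adult replicate 1, 3 or 4 or aged replicate 5 (0.0508 to 0.0680). Without both aged replicates 3 and 6, the arrays of highest lymphocyte marker score, Sdha (0.131), Uqcrc1 (0.0796), Uqcrc2 (0.0816), Atp5f1b (0.0608) and the complex II list (-0.12, 0.0677) did not pass. Other lists passed with smaller means: -0.06 for all nuclear-encoded subunits (0.00393), -0.06 for complex I (0.0451) and -0.07 for ATP synthase (0.0447). Complexes III and IV then had means of -0.08 (0.162) and -0.01 (0.548). Uqcrc2 did not pass by its brightest probe sets (0.124). The permutation call of complex II was lost without any 1 adult array (0.0569 to 0.0853). Of all 43 list scores, 0 passed the permutation test without adult replicate 2, 3, 4 or 6 and 7 without adult replicate 1, against 16 on all arrays. At an unadjusted permutation p under 0.05 there were 20 to 23 without adult replicate 2, 3, 4 or 6, where camera passed 24 to 26 lists. Macrophage and fibroblast marker scores were higher in aged hearts by 0.69 and 0.40. With quantile normalization the complex III list passed (0.0472).

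**Figure D1:**
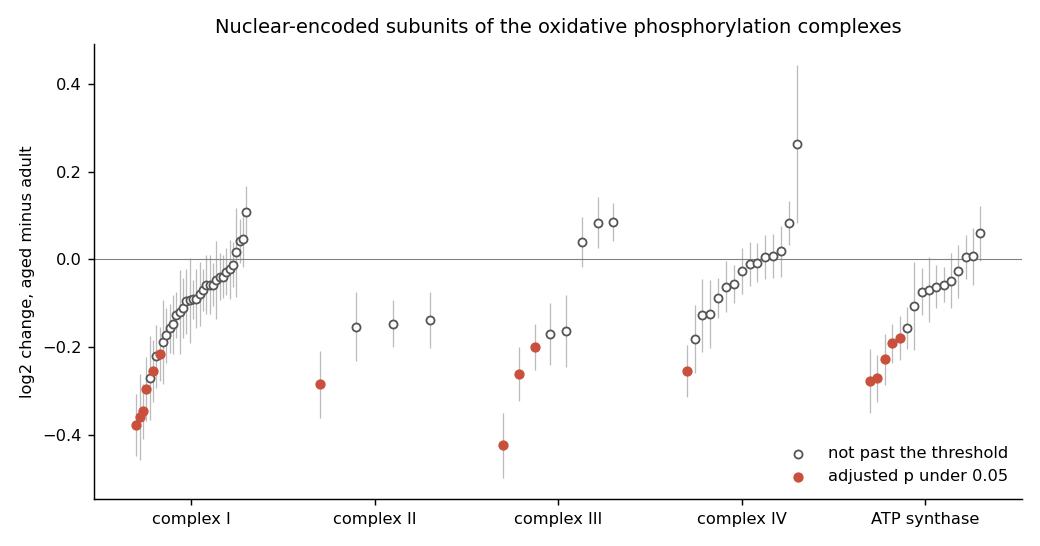
Log2 change, aged minus adult, of each measured subunit of complexes I to IV and ATP synthase (n = 5 arrays per age), with bars for the standard error and filled points for an adjusted p under 0.05. Of the 77 points, 62 lie below 0 and 16 of these are filled.

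Genes of the pathways that feed the respiratory chain were mostly lower in aged hearts. In the TCA cycle, 7 of 12 genes fell and 11 did when adjusted over the list alone, with a mean change of -15.9%. Suclg1 of succinyl-CoA ligase (-0.43 ± 0.07 SE, adjusted p = 0.00267), Idh3a of isocitrate dehydrogenase (-0.30) and the citrate synthase gene Cs (-0.28) were among them. Every aged array scored below every adult array (camera adjusted p = 2.12e-07, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). In fatty acid uptake and beta-oxidation, 10 of 26 genes fell and 15 did when adjusted over the list alone, with a mean change of -13.1%. They included Acadvl (-0.55 ± 0.07 SE, adjusted p = 0.00142), the dehydrogenase of very long chains, Mlycd (-0.54), which encodes malonyl-CoA decarboxylase. Others were Etfb (-0.42) and Etfdh (-0.41), which pass electrons to the respiratory chain. Here too the ages did not overlap in score (camera adjusted p = 3.04e-08, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). Oxidation of ketone bodies and branched-chain amino acids had the largest mean fall of the metabolic lists, -21.2%, with 9 of 18 genes fallen and 12 adjusted over the list alone. Bckdk, the kinase of the branched-chain dehydrogenase complex, fell by 0.65, Ivd by 0.53 and Acat1 by 0.39. The list had a camera adjusted p of 4.05e-08 (adjusted p = 0.368 with an estimated correlation, 0.0244 by permutation). Genes of pyruvate oxidation moved in both directions. Besides Pdp2, the subunit gene Pdhb (-0.24) and the kinase genes Pdk1 (-0.40) and Pdk2 (-0.23) fell, while the kinase gene Pdk3 rose (0.22, with probe sets at 0.01 and 0.44). Phosphatase and kinases act on pyruvate dehydrogenase in opposite ways, the former activating it and the latter inhibiting it. That made 4 of 13 genes fallen and 1 risen, or 5 and 1 adjusted over the list alone. The list mean was -0.17 (camera adjusted p = 0.0446, adjusted p = 0.499 with an estimated correlation, 0.0427 by permutation). In glucose uptake and glycolysis, the phosphofructokinase gene Pfkm (-0.43) and Gpi (-0.28) were the 2 of 18 genes that fell, also when adjusted over the list alone. The glucose transporter gene Slc2a4 did not pass (-0.56 ± 0.18 SE, adjusted p = 0.0674). The list's mean was -0.15 (camera adjusted p = 0.00294, adjusted p = 0.410 with an estimated correlation, 0.0683 by permutation). Macrophage and fibroblast marker scores were higher over the same aged arrays, by 0.69 and 0.40. The permutation call was lost without any 1 adult array for the TCA cycle (0.0525 to 0.0683), the ketone body and branched-chain list (0.0569 to 0.0731) and pyruvate oxidation (0.0525 to 0.0853). It was lost without adult replicate 2, 3, 4 or 6 for the fatty acid list (0.0525 to 0.0683), and without aged replicate 3 for pyruvate oxidation (0.0569). The pyruvate list did not pass without adult replicate 3 (0.0635), 4 (0.0760) or 6 (0.0651) or aged replicate 3 (0.197). Gene calls were lost for Pdhb without adult replicate 3 (0.0514), for Pdk1 and Pdk2 without adult replicate 2 or 3 or aged replicate 5 (0.0510 to 0.0652), and for Gpi without adult replicate 2, 3 or 4 or aged replicate 3, 4 or 5 (0.0573 to 0.0791). Slc2a4 passed without aged replicate 2 (0.0363) or 4 (0.0398), with quantile normalization (0.0412) or with array weights (0.0484). Without aged replicates 3 and 6 together, the pyruvate list (-0.10, 0.258), Pdhb (0.0886), Pdk1 (0.0516) and Pdk2 (0.0856) did not pass, and the ketone body and branched-chain list had a mean of -0.23 (2.36e-06), against -0.34 on all arrays. With array weights the pyruvate list did not pass (0.102).

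**Figure D2:**
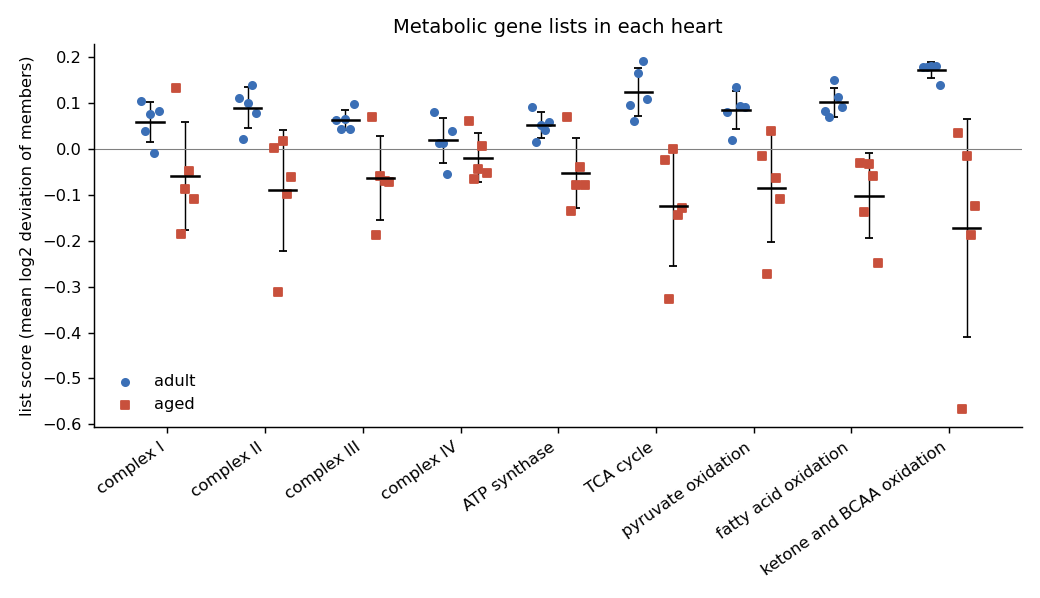
List score per array (mean over member genes of the log2 value minus the gene's mean over 10 arrays) for 9 metabolic gene lists in adult and aged hearts, with a black line for the mean and bars for the SD (n = 5 per age). Aged replicate 3 is lowest for the TCA cycle, at -0.33, where the 5 adult arrays lie between 0.06 and 0.19.

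Among genes that build and supply the mitochondrion, the lists of biogenesis regulators, carriers, assembly factors and mitochondrial ribosomal proteins passed camera as lower. By permutation the regulators and carriers alone passed. These lists were not tested together. Of the regulators of mitochondrial biogenesis, Ppargc1b (-0.68 ± 0.12 SE, adjusted p = 0.00508) and Ppargc1a (-0.62 ± 0.14 SE, adjusted p = 0.0132), which encode the PGC-1 coactivators, fell. With the estrogen-related receptor genes Esrra (-0.29) and Esrrg (-0.29), 4 of 19 fell, or 6 adjusted over the list alone. The 3 probe sets of Ppargc1a ranged from -1.16 to -0.17. The regulators' scores did not overlap between the ages (mean -0.14, camera adjusted p = 0.00207, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). Among mitochondrial carriers and phosphotransfer proteins, the creatine kinase gene Ckm (-0.43) and the aspartate-glutamate carrier gene Slc25a12 (-0.39) were among 6 of 19 that fell. Another 1 rose, the counts were 10 and 1 adjusted over the list alone, and the list passed (mean -0.17, camera adjusted p = 7.29e-05, adjusted p = 0.410 with an estimated correlation, 0.0427 by permutation). Assembly factors of the complexes had 6 of 39 genes fallen by either count, also adjusted over the list alone, led by Ecsit (-0.53) and Uqcc1 (-0.40). Their mean was -0.10 (camera adjusted p = 0.00125, adjusted p = 0.499 with an estimated correlation, 0.110 by permutation). Of the mitochondrial ribosomal proteins, 14 of 74 fell, as many when adjusted over the list alone, including Mrpl2 (-0.49) and Mrps35 (-0.41). They averaged -0.11 (camera adjusted p = 9.92e-06, adjusted p = 0.543 with an estimated correlation, 0.165 by permutation). In mitochondrial dynamics and mitophagy, 5 of 17 genes fell, among them the mitophagy kinase gene Pink1 (-0.46) and Mief2 (-0.29). Adjusted over the list alone 5 fell and 2 rose, but the list did not pass (mean -0.06, camera adjusted p = 0.235). Its mean was -0.03 without aged replicate 3 (0.442) and -0.04 without aged replicates 3 and 6 (0.416). Antioxidant genes were mixed. The extracellular peroxidase gene Gpx3 (0.81) and the regulator gene Nfe2l2 (0.33) were among 6 of 28 that rose, and the mitochondrial genes Prdx5 (-0.43) and Txn2 (-0.37) were among 3 that fell. The counts were 6 and 3 adjusted over the list alone as well, and the list did not pass (mean 0.12, camera adjusted p = 0.0997). The assembly factors had a mean of -0.06 without aged replicate 3 (adjusted p = 0.0414). Without aged replicates 3 and 6 together, their mean was -0.04 (adjusted p = 0.154), that of the mitochondrial ribosomal proteins was -0.06 (adjusted p = 0.0157), and Ppargc1a (0.0717), Esrra (0.0668) and Esrrg (0.165) did not pass. The antioxidant list passed without adult replicate 1 (0.0474). The call of Esrra was lost without adult replicate 3 (0.0547), and that of Esrrg without adult replicate 1, 3, 4 or 6 or aged replicate 3, 5 or 6 (0.0543 to 0.108) with each array centred on its median (0.0508) or by its brightest probe sets (0.0543). Permutation calls were lost without any 1 adult array for the biogenesis regulators (0.0525 to 0.0731) and the carriers (0.0525 to 0.0898), and without aged replicate 3, 5 or 6 for the carriers (0.0569 to 0.0602). Over the same aged arrays, macrophage and fibroblast marker scores were higher by 0.69 and 0.40.

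Most matrix and inflammation genes had higher means in aged hearts, and most genes of calcium handling and contraction had lower means. Most of these genes did not pass the test singly. Of the cardiac fetal program, Nppa, Nppb and Myh7 rose and Myh6 fell. In the extracellular matrix list, 14 of 35 genes rose (15 adjusted over the list alone) with a mean change of 30.1%. Among them were, besides Postn and Ccn2, the proteoglycan gene Bgn (0.97 ± 0.16 SE, adjusted p = 0.00427) and the collagen crosslinking gene Loxl1 (0.84 ± 0.11 SE, adjusted p = 0.00119). The score was higher in every aged array than in every adult array (camera adjusted p = 1.25e-07, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). In inflammation and complement, 13 of 32 genes rose and 19 did when adjusted over the list alone, with a mean change of 32.9%. Vcam1 and Cxcl13 led them, followed by the complement protease gene C1s (0.65) and the adhesion gene Icam1 (0.44). The camera adjusted p was 3.04e-08 (adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). Of the genes of cardiac hypertrophy and the fetal program, Nppb (1.12 ± 0.17 SE, adjusted p = 0.00267), which encodes brain natriuretic peptide, rose with Nppa. Myh7, the slow beta myosin heavy chain, rose as well (0.76 ± 0.16 SE, adjusted p = 0.0115), while Myh6 and Fhl2 (-0.46) fell. Lower Myh6 with higher Nppb and Myh7 is the direction of the stress programme described below. In the list tests, however, the fall of Myh6 counts against the rises. In all 6 of 23 rose and 3 fell, or 8 and 3 adjusted over the list alone. That list did not pass camera (mean 0.23, adjusted p = 0.0775), though its score differed between the ages by permutation (0.0244). It passed without adult replicate 4 (0.0484), without aged replicates 3 and 6 together (0.0460) or without dim probe sets (0.0476). In calcium handling and contraction, 8 of 32 genes fell, and adjusted over the list alone 14 fell and 1 rose. The junctional protein gene Jph2 (-0.58), the ryanodine receptor gene Ryr2 (-0.55), the sarcomere gene Actn2 (-0.46) and the calsequestrin gene Casq2 (-0.44) were those with the smallest p. The mean change was -12.1% (camera adjusted p = 1.70e-06, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). Permutation calls were lost without any 1 adult array for the matrix and calcium lists, and without adult replicate 2, 3, 4 or 6 for the inflammation and fetal program lists (0.0525 to 0.0683). Macrophage and fibroblast marker scores, described below, were higher over the same aged arrays by 0.69 and 0.40.

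**Figure D3:**
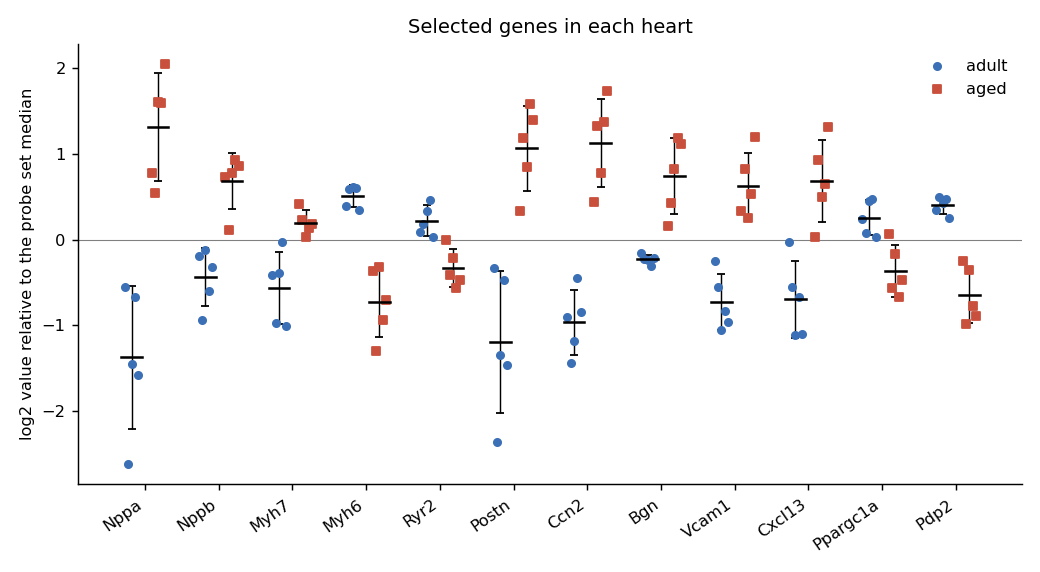
Log2 value relative to the median of 10 arrays for 12 named genes in adult and aged hearts, each point an array, with the mean and SD (n = 5 per age). Nppa has group means of -1.37 in adult and 1.31 in aged hearts, and Myh6 of 0.51 and -0.73.

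Markers of several cell types moved with age, in particular those of macrophages and fibroblasts. Of 16 macrophage markers 10 rose and 15 did when adjusted over the list alone, with a mean change of 61.4%. Among them were Fcer1g (1.01) and Tyrobp (0.98), which encode signaling adaptors of myeloid cells. The macrophage score ran from -0.05 in aged replicate 2 to 0.89 in aged replicate 6 (camera adjusted p = 1.78e-08, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). All 15 fibroblast markers had higher means in aged hearts, and 8 rose (9 adjusted over the list alone), including Mfap4 (0.90) and the matrix protein gene Dpt (0.70). The mean change was 31.6% (camera adjusted p = 2.24e-07, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). Of 11 atrial myocyte markers, Nppa and the atrial light chain gene Myl7 (1.45 ± 0.37 SE, adjusted p = 0.0261) rose and 9 did not pass. Adjusted over the list alone 2 rose and 1 fell, and the list mean was 0.40 (camera adjusted p = 0.0373, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). Ventricular markers had Kcne1 (0.50) and Myh7 as 2 of 8 that rose, or 2 risen and 1 fallen adjusted over the list alone. They had a mean of 0.09, a median of -0.04 and a camera adjusted p of 0.902. The endothelial genes Vwf (0.94) and Tek (0.35) were 2 of 16 that rose, or 3 adjusted over the list alone. That list passed camera (mean 0.17, camera adjusted p = 0.0318, adjusted p = 0.446 with an estimated correlation, 0.0539 by permutation). In smooth muscle and pericytes Smtn fell (-0.26) and Cspg4 rose (0.22), as they did adjusted over the list alone, among 13 markers with a mean of -0.01 (camera adjusted p = 0.868). The granzyme gene Gzmb (1.46 ± 0.42 SE, adjusted p = 0.0430) was the 1 of 14 lymphocyte markers that rose, whereas 4 rose and 1 fell adjusted over the list alone. The list did not pass (mean 0.24, camera adjusted p = 0.576, and 0.09, adjusted p = 0.416, without aged replicates 3 and 6). These 2 arrays were left out for their high score on this same list. A lower list mean without them therefore follows from the choice, and a lower value of its member Gzmb is favoured by it. The calprotectin gene S100a9 (1.08) was the 1 of 10 markers of neutrophils and mast cells that rose, also adjusted over the list alone (mean 0.18, camera adjusted p = 0.235). The mean was 0.12 without aged replicate 6 (0.156) and 0.09 without aged replicates 3 and 6 (0.416). Erythroid markers had a mean of 0.11 (camera adjusted p = 0.632) and scored 0.87 in aged replicate 6, where the highest adult array had 0.20. The direction of that mean turned without aged replicate 6 (-0.10, adjusted p = 0.370) and without aged replicates 3 and 6 together (-0.20, adjusted p = 0.0457). The mean also ranged from 0.04 to 0.22 without single other arrays and was 0.01 with quantile normalization and 0.02 with array weights. Among 15 adipocyte markers 1 fell, also adjusted over the list alone (mean -0.12, camera adjusted p = 0.176). Adult replicate 2 scored 0.78 while the other adult arrays lay between -0.17 and -0.09, and without it the direction of the mean turned (0.06, adjusted p = 0.722). With quantile normalization the mean was -0.07. The remaining marker lists did not pass camera, with adjusted p of 0.60 for skeletal muscle (mean -0.03, where Ckm fell) and 0.715 for Schwann cells and neurons (mean 0.00). The values were 0.715 for mesothelium and epicardium (mean -0.06, where 1 of 8 rose) and 0.491 for lung, liver and thymus (mean -0.03). Their counts were the same adjusted over the list alone. The mesothelial mean ranged from -0.10 to 0.00 without single arrays, and the skeletal muscle mean was -0.05 without aged replicates 3 and 6 (0.209). The means of smooth muscle and of Schwann cells and neurons, close to 0, changed sign with single arrays and stayed within 0.03 of 0. The atrial list did not pass without adult replicate 1 (0.0597) or aged replicate 2 (0.0518) or 4 (0.0708). Nor did the endothelial list pass without adult replicate 4 (0.0629) or aged replicate 2 (0.112) or 3 (0.0593). With array weights neither passed (0.0502 and 0.102), nor did the endothelial list by the brightest probe sets (0.0553). Permutation calls were lost without any 1 adult array for macrophages and fibroblasts (0.0525 to 0.0731), and without adult replicate 2, 3, 4 or 6 for the atrial list (0.0525 to 0.0683). Calls were lost for Myl7 without adult replicate 2, 3 or 4 or aged replicate 4, 5 or 6 (0.0524 to 0.0684) with quantile normalization (0.0762) or the robust fit (0.0576), and for Vwf without adult replicate 3 (0.0616). Vwf gave 0.51 without aged replicates 3 and 6 (0.0200). They were also lost for Cspg4 without adult replicate 1, 2, 3 or 6 or aged replicate 3 or 4 (0.0510 to 0.0714) or without aged replicates 3 and 6 together (0.0844). That of S100a9 was lost without adult replicate 2, 3, 4 or 6 (0.0535 to 0.0652) or with the robust fit (0.0525). Gzmb was not called when any 1 adult array or aged replicate 3 or 6 was left out (0.0509 to 0.102), and leaving out both of the latter left it at 0.66 (adjusted p = 0.0609). Gzma then gave 1.31 (adjusted p = 0.0135). Gzmb was not called with array weights (0.0569) or the robust fit (0.0869) either.

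**Figure D4:**
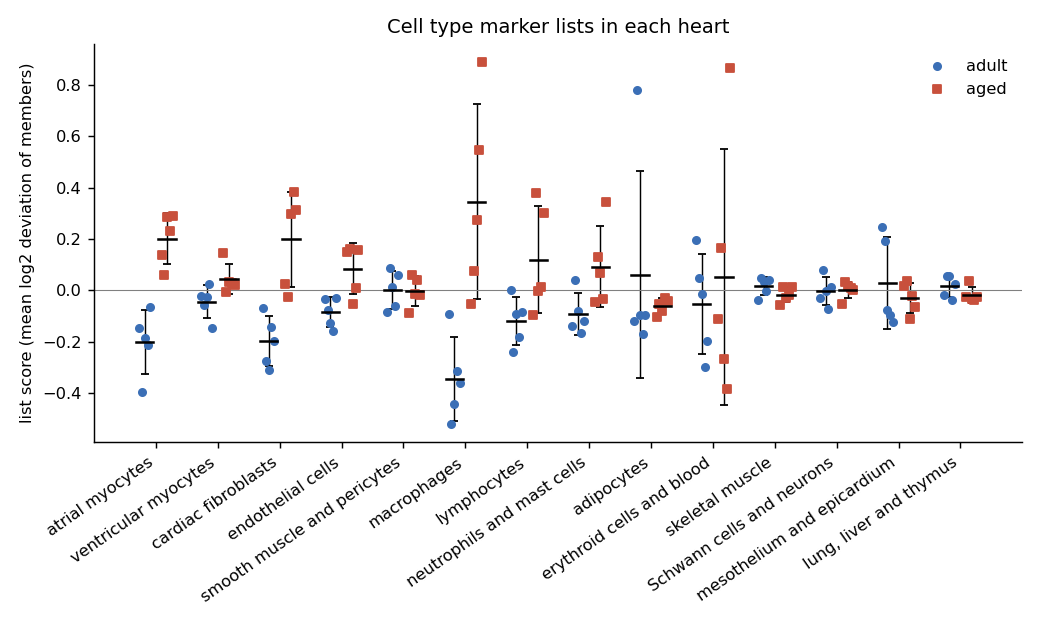
List score per array (mean over marker genes of the log2 value minus the gene's mean over 10 arrays) for 14 cell type marker lists in adult and aged hearts, with a line for the mean and bars for the SD (n = 5 per age). Macrophage scores average -0.35 in adult and 0.35 in aged hearts, and smooth muscle and pericyte scores 0.00 and 0.00.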

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

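All tests of explanations in this part were chosen after the result they bear on was seen, while Dixon's criterion for arrays that stand apart and the marker lists were fixed beforehand.

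Some genes of cytotoxic lymphocytes, but not all, were high in 2 of the 5 aged hearts. A list of 18 such genes, written after this was seen, with 17 measured and 3 of them also in the lymphocyte or inflammation lists, scored 1.06 in aged replicate 3 and 0.855 in aged replicate 6 against at most 0.0787 in the other 8 arrays. Gzmb read 2.23 and 2.18 there and the perforin gene Prf1 2.55 and 2.25. Gzma read 3.38 and 1.20, but with 1.19 in aged replicate 2 it did not set aged replicate 6 apart. Ncr1 (0.151 and 0.0191), Klrk1 (0.0285 and -0.0506), Ncr3 (0.159 and -0.14) and Ctsw (-0.126 and -0.171) stayed near 0. Prf1 and these 4 were named after their values were seen, and 5 of the 17 genes rose with age. More blood of the usual make-up was argued against as the whole cause in aged replicate 3. There the erythroid score lay above the adult mean by 0.217 and the cytotoxic score by 1.42 (difference -1.20, adult SD 0.229). It stays open in aged replicate 6, where these were 0.918 and 1.21 (difference -0.29). The difference was not particular to aged replicate 3. Every aged array lay below every adult array on it, and aged replicate 5, with a cytotoxic score of 0.0787, had -0.764. A dividing population of cytotoxic lymphocytes is a candidate that stays open, since the proliferation list, already scored when this test was chosen, gave 0.458 and 0.246 in these arrays against at most -0.0482 in the other 8.

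Of 11 atrial myocyte markers, Nppa and Myl7 rose in aged hearts, and the call of the list was lost with an estimated correlation (adjusted p = 0.318), with array weights (0.0502) or without adult replicate 1 (0.0597) or aged replicate 2 (0.0518) or 4 (0.0708). A larger share of atrial tissue in the aged samples was not borne out by the 9 other atrial markers. Their difference was 0.0319 ± 0.0651 (mean and SE over genes), below 0.723, the midpoint between 0 and the change of Myl7. That mark was set after the values were seen. How far each marker would rise with added atrial tissue is not known from these data, so this explanation stays open. The atrial light chain gene Myl4 and the sarcolipin gene Sln, both named after their values were seen, gave 0.255 (adjusted p = 0.151) and 0.159 (adjusted p = 0.507). A stress programme of ventricular myocytes is left open for Nppa, because the 4 of its 5 genes that passed in its direction, Nppb, Myh7, Myh6 and Ankrd1 (0.463, adjusted p = 0.0127), came from the fetal program list reported above and could not test it, and Acta1 gave 0.335 (adjusted p = 0.076). Myl7 was not among these 5 genes, and what raised it stays open.

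TCA cycle and fatty acid oxidation genes, 38 in the combined lists, scored lower in every aged heart than in every adult heart, with a difference of -0.218 (exact permutation p = 0.00794, the smallest that these arrays allow). A lower share of cardiac myocytes through a loss of myocytes alone would raise the markers of the other cell types alike. The fibroblast score instead rose by 0.403 more than the smooth muscle and pericyte score (exact permutation p = 0.0238). Both scores were known when the test was chosen. A rise of fibroblast genes beside a loss of myocytes would give this difference too, so it cannot decide on such a loss, which stays open. The calcium handling and contraction list was lower as well (mean -0.19), while the ventricular myocyte markers had a mean of 0.09. A lower share of myocytes through a gain of fibroblasts or macrophages is not tested by this difference and stays open. A shift with signal that is shared by bright probe sets was argued against. Relative to the median of 2523 genes outside the metabolic lists classed as bright, the score still differed by -0.211 (exact permutation p = 0.00794). The classes are the approximate ones of the numerical step. A shift of the very brightest probe sets alone could not be seen, because this class has no upper border. Lower expression of the mitochondrial biogenesis regulators is a candidate that stays open, since their score differed by -0.145 (exact permutation p = 0.00794). That score was known when the test was chosen and cannot separate a cause from a parallel change with age.

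One array stood apart from the other 4 of its age, by a gap above 0.71 of the group's range, in 18 of 330 groups tested over 121 genes, 43 list scores and the array medians (5.45%, where chance gives about 1 in 20). In aged replicate 3, Bcat2 read -1.49 (the other aged arrays -0.323 to -0.131), Pfkm -0.456 (-0.193 to -0.129), Ckm -0.65 (-0.249 to -0.1) and Nppb 0.118 (0.733 to 0.928). Its lung, liver and thymus score was 0.0375 (-0.0355 to -0.0254). In aged replicate 2, Mlf1 read -0.144 (-0.767 to -0.61), the complex I gene Ndufb7 0.0411 (-0.359 to -0.295) and the ventricular myocyte score 0.146 (-0.00612 to 0.0321). In aged replicate 6, S100a9 read 2.13 (0.214 to 0.539) and Maff, an immediate early gene, 0.671 (0.171 to 0.298). In adult replicate 4, Sdha read 0.263 (the other adult arrays 0.00756 to 0.0388), Atp5f1b 0.109 (0.0427 to 0.0592) and Cspg4 0.0366 (-0.213 to -0.188). In adult replicate 3, Pdk2 read 0.253 (0.059 to 0.113), Cpt2, the inner carnitine palmitoyltransferase gene, 0.15 (0.0474 to 0.0593) and Acat1 0.0393 (0.212 to 0.281). The adipocyte score of adult replicate 2 was 0.781 (-0.168 to -0.0941), and the ketone body and branched-chain amino acid score of adult replicate 6 was 0.141 (0.178 to 0.181).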

How the results depend on the processing

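The alternatives chosen only after the data were seen were leaving out dim probe sets, the brightest probe sets of each gene, the robust eBayes fit, leaving out the 2 aged arrays of highest lymphocyte score, and leaving out arrays for list scores and array medians. The count of genes kept within 1.5 times of 1686 with quantile normalization (1815), array centring (1666), without dim probe sets (1719), with the robust fit (1679), with array weights (2239) and with the brightest probe sets (1746). The classes behind the dim and brightest settings are inferred and approximate. For the 199 genes that met the rules for naming, not all of them named in the text, 18 settings gave 3579 values. Of these, 3274 kept their side of the threshold, 266 no longer passed, 39 newly passed and 0 reversed by limma. Of 860 values for the lists, 781 kept their side, 65 no longer passed, 13 newly passed and 1 reversed, passing in the other direction. Values that passed in neither setting were counted as kept even where the sign changed. An example is the adipocyte list without adult replicate 2 (0.058, against -0.122 on all arrays). Of 559 values for the list scores, the numbers were 462, 79, 18 and 0 by the exact permutation test. The cause was not tested for any change below except where fewer arrays or another threshold make it by construction. The planned filter on mean level, the eBayes trend and the control probe set families were not run, because the values are centred and hold no control probe sets. Pseudocounts were not needed for log values.

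With quantile normalization complex III gave -0.117 (adjusted p = 0.0472), and with array weights pyruvate oxidation gave -0.146 (adjusted p = 0.102). Without the 2 aged arrays of highest lymphocyte score, replicates 3 and 6, 1526 probe sets (543 lower) and 1012 genes (356 lower) were called. All nuclear-encoded subunits then gave -0.0574 (adjusted p = 0.00393), complex I -0.0599 (adjusted p = 0.0451), ATP synthase -0.0687 (adjusted p = 0.0447), complex II -0.117 (adjusted p = 0.0677), pyruvate oxidation -0.0977 (adjusted p = 0.258), and the erythroid markers, which had a mean of 0.106 on all arrays, reversed to -0.202 (adjusted p = 0.0457). At an adjusted p under 0.10, 3925 probe sets (2104 higher, 1821 lower) and 2590 genes (1164 lower) passed. Adding a change of at least 1.5-fold left 483 probe sets (329 higher, 154 lower) and 248 genes (192 higher, 56 lower). With an unadjusted p under 0.05 the counts were 6783 probe sets (3363 higher, 3420 lower) and 3738 genes (2032 higher, 1706 lower). The share of called genes that were higher was 57.1%, and 59.7% with quantile normalization.

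With an estimated correlation 0 lists passed camera (5 at an unadjusted p under 0.05), where 25 passed with the preset one and 16 by fry. The values were -0.118 for complex I (adjusted p = 0.530), -0.181 for complex II (0.446), -0.105 for ATP synthase (0.446), -0.104 for all nuclear-encoded subunits (0.499), -0.249 for the TCA cycle (0.318), -0.169 for pyruvate oxidation (0.499) and -0.203 for fatty acid oxidation (0.318). Fry, which asks whether a list moves on balance one way and not whether it differs from other genes, did not pass complex I (-0.118, adjusted p = 0.144), complex II (-0.181, 0.0587), pyruvate oxidation (-0.169, 0.151) or all nuclear-encoded subunits (-0.104, 0.0923). By the exact permutation test 16 lists passed, without complex I (-0.118, adjusted p = 0.118), ATP synthase (-0.105, 0.0742) or all nuclear-encoded subunits (-0.104, 0.0853). With the median over members the pyruvate score gave -0.149 (0.0683).

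With 1 array left out, the probe sets called ranged from 1481 to 2943 (higher 819 to 1600, lower 619 to 1452) and the genes from 988 to 1994 (higher 558 to 1059, lower 406 to 940). List means and scores, which are the same number, ranged from -0.166 to -0.0871 for complex I, -0.208 to -0.125 for complex II, -0.160 to -0.0954 for complex III, -0.0577 to -0.0217 for complex IV, and -0.135 to -0.0840 for ATP synthase. They ranged from -0.140 to -0.0773 for all nuclear-encoded subunits, -0.281 to -0.199 for the TCA cycle, -0.199 to -0.122 for pyruvate oxidation and -0.221 to -0.166 for fatty acid oxidation. Of the list scores, 15 to 28 passed the permutation test without 1 aged array, 7 without adult replicate 1 and 0 without adult replicate 2, 3, 4 or 6. In these last 4 settings 20 to 23 had an unadjusted permutation p under 0.05, and camera passed 24 to 26 lists. The smallest possible p was 0.00794 in all 10 settings, and 2 to 3 scores reached it in those 4, against 13 to 18 without an aged array. With unequal groups, scores that do not overlap between the ages need not reach it. The TCA cycle without adult replicate 2 is an example (-0.265, permutation adjusted p = 0.0525). Losses in these settings thus cannot show that a list rests on 1 array. The aged minus adult difference of array medians ranged from -0.00857 to -0.00455.

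The adult and aged groups share 4 replicate numbers, and the deviations of same-numbered arrays correlated at 0.006 to 0.137. Of these 8 arrays, 1 correlated best with its own number. The values give little sign of pairing but cannot exclude a shared batch, which the labels do not state. With the replicate block, 1640 probe sets (597 lower) and 1069 genes (348 lower) were called, and 67.4% of the genes called were higher. Of the 199 genes that met the rules for naming, 41 no longer passed by limma and 1 newly passed. Among the former were Ppargc1a (adjusted p = 0.0586), Sdha (0.0527), Atp5f1b (0.107), Uqcrc1 (0.0653), Cox5a (0.0777) and Pdhb (0.0740). The fetal program list (0.251, camera adjusted p = 0.0459) and the antioxidant list (0.144, 0.0236) newly passed. The proteasome list gave -0.0549 (adjusted p = 0.0459), against -0.0868 without the block.

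Of 100 splits of the 10 arrays into 5 and 5, 1, the real one, gave as many probe sets (2492, highest other 5). Likewise 1 gave as many genes (1686, highest other 0 by limma). Chance is thus an unlikely source of both counts, to a precision of 1 in 100. The splits cannot tell age from batch or scan date, which the labels do not state. As many lists passed camera in 9 of the 100 splits (25 in the real one, highest other 28), so chance cannot be excluded for the number of lists. Most of the others among these 9 exchange only 1 adult and 1 aged array, so they still carry much of the difference between the ages. With adult replicate 3 and aged replicate 5 exchanged, 27 lists passed. The median of the other splits was 13 lists, so a camera call alone does not set age apart from another grouping of the arrays.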

Other observations

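The lists of this part were fixed beforehand, and the tests chosen after the result was seen were those without the 2 aged arrays of highest lymphocyte score, those of list scores with 1 array left out, and the one on the brightest probe set of Cdkn1b.

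Genes for cytosolic ribosomal proteins were higher in aged hearts almost throughout. Of 31 measured, 25 rose and 26 did when adjusted over the list alone, with a mean change of 21.6%, and every aged array scored above every adult array. Rpl3 (0.62 ± 0.08 SE, adjusted p = 0.00131) and Rpl34 (0.45 ± 0.06 SE, adjusted p = 0.00111) were among them (list camera adjusted p = 2.21e-18, adjusted p = 0.318 with an estimated correlation, 0.0244 by the exact permutation test). The permutation call was lost without adult replicate 2, 3, 4 or 6 (0.0525 to 0.0683). The mitochondrial ribosomal genes described above had a mean change of -7.42% over the same arrays, and macrophage and fibroblast marker scores were higher by 0.69 and 0.40. Of the 30 proteasome genes, Psma7 (-0.36) and Psmd7 (-0.21, with probe sets at -0.42 and 0.00) fell. Adjusted over the list alone 1 fell, and the mean was -0.09 (camera adjusted p = 0.00176, adjusted p = 0.498 with an estimated correlation, 0.101 by permutation). Psmd7 was not called without adult replicate 1, 2, 3 or 4 or aged replicate 4, 5 or 6 (0.0603 to 0.0917), nor without aged replicates 3 and 6 together (0.0816). In heat shock and the unfolded protein response, 5 of 31 genes rose, including the stress transcription factor gene Atf3 (0.56), and 2 fell, or 7 and 2 adjusted over the list alone. The list did not pass (mean 0.08, camera adjusted p = 0.189) except without aged replicate 3 (0.0277) or without aged replicates 3 and 6 (0.0460), and its mean was 0.05 without aged replicate 6 (0.370).

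Core clock genes moved in opposite directions. Bmal1, the activating partner of the clock, fell by 0.61 (SE 0.0853, adjusted p = 0.00177), while its output gene Dbp (0.87), the repressor gene Bhlhe41 (0.57) and Per2 (0.37, with probe sets at -0.13 and 0.88) rose. In all 5 of 17 clock genes rose and 3 fell, or 5 and 4 adjusted over the list alone, with a mean of 0.04 (camera adjusted p = 0.715). The mean was 0.03 without aged replicate 4 (0.929) and 0.08 without aged replicates 3 and 6 (0.336). The labels give no time of day for either age. Immediate early genes were higher, with 8 of 24 risen and 10 adjusted over the list alone, among them Nr4a1 (0.63) and Maff (0.58). Their mean change was 15.5% (camera adjusted p = 0.000193, adjusted p = 0.318 with an estimated correlation, 0.0244 by permutation). It was 0.14 in log2 without aged replicates 3 and 6 (adjusted p = 0.00939), against 0.21 with them. Macrophage and fibroblast marker scores were higher over the same arrays, by 0.69 and 0.40. The permutation call of the immediate early genes was lost without adult replicate 2, 3, 4 or 6 (0.0525 to 0.0683).

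Of the genes of the interferon response and antigen presentation, 7 of 32 rose and 13 did when adjusted over the list alone, such as the antiviral genes Mx1 (0.65) and Oas1a (0.46). The mean change was 19.8% (camera adjusted p = 5.18e-06, adjusted p = 0.480 with an estimated correlation, 0.0919 by permutation). Mx1 and Oas1a were not called without adult replicate 2 or 3 or aged replicate 5 or 6 (0.0541 to 0.0773), nor Mx1 without adult replicate 4 (0.0555). Without aged replicates 3 and 6 together neither was called (both 0.112). Aged replicate 6 scored highest, at 0.43, as it did for macrophage markers (0.89), and its lymphocyte marker score (0.30) was second only to that of aged replicate 3. For the interferon list adult replicate 1, at 0.14, lay above 3 of the aged arrays. Of 25 proliferation genes, Pcna rose (0.38, adjusted p = 0.0335), but 0 passed adjusted over the list alone by limma, where 4 had an unadjusted p under 0.05. The mean change of 13.8% (camera adjusted p = 0.00121, adjusted p = 0.543 with an estimated correlation, 0.201 by permutation) was carried by aged replicates 3 and 6. Without aged replicate 3 the list gave 0.0949 (adjusted p = 0.0625), and without both it gave 0.0133 (adjusted p = 0.732). With array weights it gave 0.123 (adjusted p = 0.0225). Pcna was not called without adult replicate 2, 3 or 4 or aged replicate 3, 5 or 6 (0.0501 to 0.0826). Without aged replicates 3 and 6 together it gave 0.25 (adjusted p = 0.168). Among 19 senescence and cell-cycle inhibitor genes, Gadd45b (0.34) and Igfbp7 (0.40) rose and Cdkn1b (-0.27, but -0.06, adjusted p = 0.684, by its brightest probe set) and Gadd45g (-0.51) fell, as they did adjusted over the list alone. The list did not pass (mean 0.04, camera adjusted p = 0.549, and 0.02, adjusted p = 0.789, without adult replicate 6). Gadd45g was not called without adult replicate 3, 4 or 6 or aged replicate 4, 5 or 6 (0.0514 to 0.0632), and Gadd45b was not without aged replicates 3 and 6 together (0.30, adjusted p = 0.0615).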
